A study of Mus musculus with 37 samples.

How the data were processed

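The samples were 37 temporal lobes of mice, taken from wild-type (WT) animals and from animals lacking Wfs1 (KO) in strains that the labels call C57 and 129SV. The series design writes the same backgrounds as C57B6 and 129S6, and they are called C57 and 129 here. Per the labels, the tissue was dissected under a microscope and frozen, total RNA was taken with Trizol, and biotin-labelled cRNA was made with a one-cycle kit. It was measured on Affymetrix mouse expression arrays. There were 9 C57 WT, 9 C57 KO, 9 129 WT and 10 129 KO arrays. The labels give neither sex, age, litter nor hybridization day, and they do not say in so many words that each array came from its own animal, so p-values measure the spread between samples.

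The deposited values were probe set summaries in log2 units, already normalized between arrays by the authors. MAS5 and GCRMA were both named in the submitters' notes, with neither version nor role given. The values had the form that GCRMA writes, with array medians from 4.30 to 4.36 and values reaching from 1.34 to 13.32. They were used as deposited, with no further scaling and no pseudocount. The table held 45101 probe sets without missing values, of which 64 were Affymetrix controls. Of the 45037 others, 34945 had 1 gene symbol, 932 had several and 9160 had none. Probe sets with several symbols or none were left out. Each of the 18193 genes was represented by its probe set with the highest mean over all arrays. A gene was tested when its mean in at least 1 group reached the 40th percentile of the probe set means, a log2 signal of 3.6, which left 13078 genes. Gene order along chromosomes came from the mouse RefSeq gene table and was used only for names and neighbours.

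A limma model (limma 3.58.1, R 4.3.3) with 1 mean per group was fitted to all 37 arrays. The contrasts were KO minus WT in C57, KO minus WT in 129, the mean of these, their difference, and 129 WT minus C57 WT. Genes were called at a 2-sided Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted within each contrast. Camera with an estimated correlation and fry were run as alternatives. Of 22 lists, 19 had at least 5 measured genes and were tested. They covered ER stress and the unfolded protein response, calcium stores and buffers, the growth hormone and IGF axis, GABA, glutamate, dopamine and serotonin, neuropeptides, activity-induced early genes and the mitochondrial respiratory chain. Further lists held markers of oligodendrocytes and myelin, astrocytes, microglia, vessels, choroid plexus, hippocampus, striatum, thalamus and hypothalamus, and cortical layers, and the chromosomal neighbours of Wfs1. The pituitary (4 measured), blood (2 measured) and sex-linked (4 measured) lists were too short in the filtered data. The growth hormone, pituitary, GABA and monoamine lists had been chosen with knowledge of earlier work on Wfs1-deficient mice.

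The groups, contrasts, lists, thresholds and the rule for naming genes were fixed at the outset, as were the alternatives listed next unless noted. The rule took, per comparison, the 8 largest rises and 8 largest falls among called genes (5 and 5 for the difference between strains), and up to 3 called members of each list. Clone names and predicted genes were skipped. Wfs1, Gh, Prl, Trpm8, Hspa5, Ddit3 and Gabra2 were named whatever their result. Genes near Wfs1 were compared with all others by Fisher's exact test, over 50 annotated genes on each side. Scores of a list were the mean deviation of its members from their own means, compared by 2-sided permutation tests that were exact where a group had under 10 arrays. These used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.

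Alternatives chosen before the data were examined were no filter, a filter at the 60th percentile, quantile normalization, median centring, every probe set, the mean of a gene's probe sets, eBayes with trend and robust, array weights, only the groups compared, the first residual principal component, and each array left out. A search for unlabelled batches split the arrays by their residual values on 40 genes into sets of 19 and 18 arrays. Set 1 held 4 C57 WT, 5 C57 KO, 5 129 WT and 5 129 KO arrays, and set 2 held 5, 4, 4 and 5. These sets came from the data and are not groups of the study. Array set as a block, each set alone, the first 3 residual principal components, the actin 3' to 5' difference as a covariate, the whole chromosome of Wfs1 and leaving out 3 arrays least like their group were added after the data had been seen. For each of the 5 contrasts, 100 splits of the arrays were counted, the real one included, and later another 100 drawn within the array sets.

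The method was tested on simulated data with the same group sizes and 13078 genes. Genes shifted by 0.5 on the log2 scale were recovered in 98.5% of cases in C57, 98.5% in 129 and 95.5% between strains, and genes shifted by 0.3 in 62.7%, 68.7% and 71.6%. False calls numbered 3, 5 and 8. A list shifted by -0.30 was called, with 0 other lists. The number of arrays limits the precision. The median standard error of a log2 difference was 0.08 in C57 and 0.07 in 129, and correlations between arrays ranged from 0.974 to 0.997.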

Results

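Transcript levels were compared in the temporal lobe of mice with and without Wfs1, which encodes wolframin, an endoplasmic reticulum membrane protein mutated in Wolfram syndrome. The 37 arrays formed 4 groups, with 9 C57 WT, 9 C57 KO, 9 129 WT and 10 129 KO. Signals are log2 values, differences are log2 fold changes, and adjusted p-values come from limma over 13078 genes unless a list is named. The difference between 3' and 5' actin control signals, a sign of RNA quality, ranged from 0.91 to 2.76 and was highest in 129 WT array 73. After group means were removed, the arrays fell into sets of 19 and 18 that differed in 886 of 13038 genes not used to find them. In every group set 1 held the lower sample numbers and set 2 the higher ones. The labels do not say what these numbers stand for. The gene with the largest difference between the sets was Gprin3 (2.71 higher in set 2), and Malat1, a nuclear RNA, was 1.53 higher there. Both genes were among the 40 used to find the sets.

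The Wfs1 signal was measured first, as a check of the genotypes. It was 9.32 ± 0.17 (SD, n = 9) in C57 WT and 3.03 ± 0.26 (SD, n = 9) in C57 KO. In 129 it was 9.33 ± 0.12 (SD, n = 9) in WT and 3.11 ± 0.28 (SD, n = 10) in KO. Wfs1 fell by 6.29 in C57 (SE 0.10, limma adjusted p = 2.04e-36) and by 6.22 in 129 (SE 0.10, adjusted p = 1.11e-36), in each KO array of both strains. The KO signals lay below the filter at 3.6, where background was not separated from transcript, so these are falls in signal. They would be lower limits for the falls in transcript only if the probe set reads whatever transcript remains. The falls in signal differed between the strains by -0.06 (SE 0.14, adjusted p = 0.999), which at this signal does not show that the remaining transcript was equal. A single probe set represented Wfs1, and its position relative to the targeted part of the gene is not given in the sources used here.

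**Figure D1:**
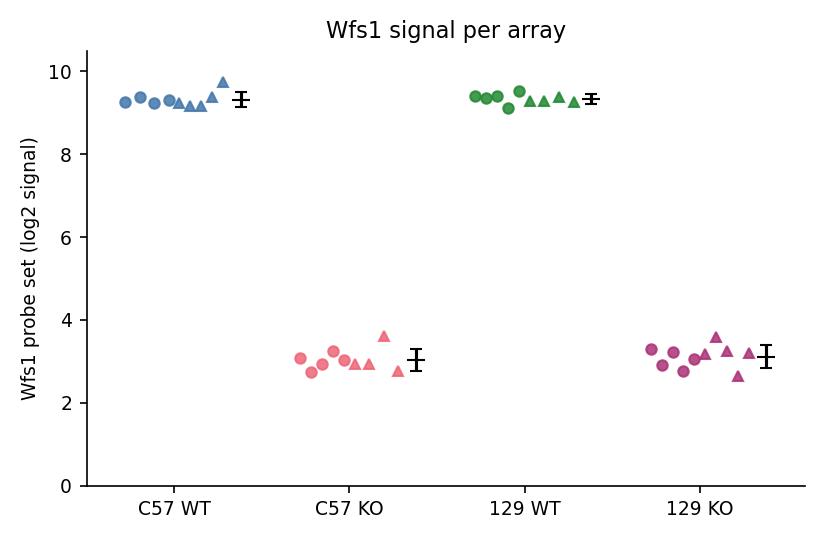
Wfs1 probe set signal (log2, vertical axis) in each array of the 4 groups, with circles for array set 1, triangles for array set 2 and bars for mean ± SD. The group means were 9.32 in C57 WT, 3.03 in C57 KO, 9.33 in 129 WT and 3.11 in 129 KO.

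The comparison of KO with WT in C57 asked which transcripts change with the loss of Wfs1 on that background. Abhd1, which encodes a protein of the alpha/beta hydrolase family, rose by 1.38 (SE 0.11, limma adjusted p = 1.68e-11), from 4.50 ± 0.37 to 5.88 ± 0.20 (SD, n = 9 and 9). Drc1, a part of the regulatory complex of motile cilia, rose by 0.64 (SE 0.07, adjusted p = 1.09e-07). Lgi2, of the family of secreted leucine-rich LGI proteins, fell by 0.61 (SE 0.10, adjusted p = 0.00272) on its brightest probe set, while its other probe set was 0.18 higher in KO and the mean of its probe sets differed by -0.21 (adjusted p = 0.523). Sod3, the extracellular superoxide dismutase, fell by 0.47 (SE 0.09, limma adjusted p = 0.0206) from a signal of 3.88 to 3.41. The latter lies below the filter at 3.6, so this too is a fall in signal, and its size in transcript is not settled. Ccr6, a chemokine receptor, fell by 0.74 (SE 0.14, adjusted p = 0.0174).

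In all, 14 genes passed in C57, 8 higher and 6 lower, and 833 had an unadjusted p under 0.05. Of the 14, 12 lie on the chromosome that carries Wfs1, Wfs1 included, and Ccr6 and Ypel1 do not. Cox18, an insertase for a subunit of cytochrome oxidase, rose by 0.39 (SE 0.08), Galnt11, which starts O-linked glycosylation, by 0.33 (SE 0.07), and Ypel1 by 0.25 (SE 0.05). Cfap69, a flagellum and cilium protein, fell by 0.59 (SE 0.13). Ppp1cb, a catalytic subunit of protein phosphatase 1, fell by 0.42 (SE 0.09) on its brightest probe set, but another of its probe sets was 0.75 higher in KO and the mean of its probe sets differed by 0.07. Adjusted p-values of these genes lay between 0.0206 and 0.0389. With the mean of probe sets the calls of Galnt11 (adjusted p = 0.451) and Ypel1 (adjusted p = 0.765) were lost. The call of Cfap69 was lost after quantile normalization (adjusted p = 0.0503), median centring (0.0574), array weights (0.0631) and without 3 arrays (0.101). With 1 array left out in turn, Abhd1, Drc1, Lgi2 and Ccr6 kept their calls, while Sod3 lost it for 3 arrays, Galnt11 and Ypel1 for 6 each, Ppp1cb for 8, Cox18 for 12 and Cfap69 for 13. Fitted on the C57 arrays alone, 6 of the 11 named genes kept their calls, and Cox18 (limma adjusted p = 0.269), Ypel1 (0.226), Ccr6 (0.304), Cfap69 (0.417) and Sod3 (0.135) lost them. Another 3 called genes with clone names rose. Among the 50 annotated genes on each side of Wfs1, 0 of 30 tested passed in limma, against 13 of 13047 elsewhere (Fisher's exact p = 1). Over the whole chromosome, a comparison added after the data were seen, 11 of 820 passed against 2 of 12257 (Fisher's exact p = 3.84e-12). Of the 13 called genes other than Wfs1, 12 differed in the same direction between 129 WT and C57 WT. That comparison shares the C57 WT arrays with this one, which by itself moves both differences the same way. In simulations without true differences, such sharing gave a correlation of 0.498 and a covariance of 0.00381 over genes. The measured values were 0.314 and 0.00442. True differences change both values, and values over all genes do not decide what sharing gave in the 13 called genes.

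**Figure D2:**
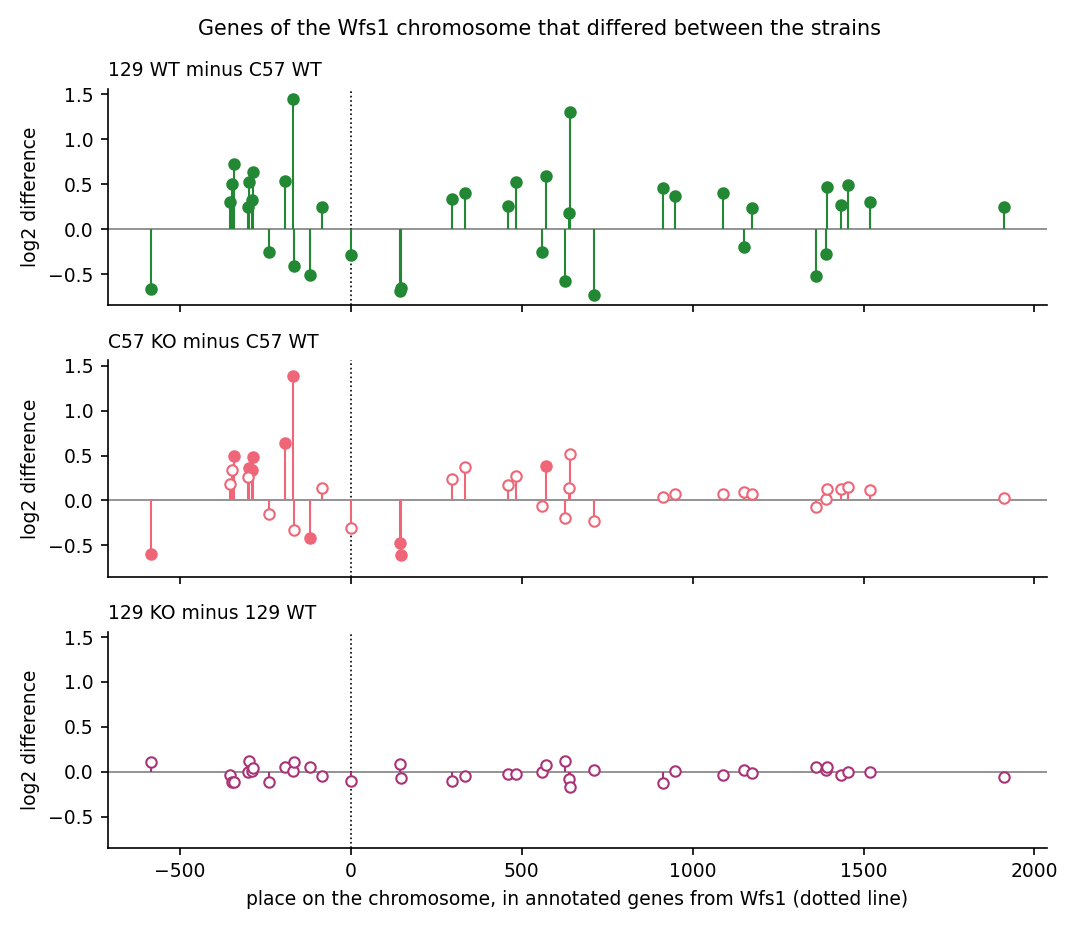
Differences (log2, vertical axes) of the 39 genes on the Wfs1 chromosome that differed between 129 WT and C57 WT, by their place in annotated genes from Wfs1 (horizontal axis), for strain (top), KO in C57 (middle) and KO in 129 (bottom), with filled points for adjusted p under 0.05. In C57 KO 37 of them had the direction of the strain difference and 11 passed, and in 129 KO 11 had it. The top and middle panels share the C57 WT arrays, which by itself turns differences the same way. The top and bottom panels share the 129 WT arrays with opposite sign, which by itself turns them the other way. The counts of 37 and 11 therefore do not by themselves measure KO effects.

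The striatum marker list gave the clearest change of a group in C57. Its 14 measured members fell together, by a mean of 0.49 (camera adjusted p = 2.24e-25, and adjusted p = 0.0227 with an estimated correlation). Adjusted over the list alone, 14 of 14 were lower, and over all genes 0 passed in limma, with 14 at an unadjusted p under 0.05. The differences were -0.77 (SE 0.19) for Gpr6, -0.60 (SE 0.15) for Pde10a, the main phosphodiesterase of medium spiny neurons, -0.59 (SE 0.18) for Drd2, the D2 dopamine receptor, and -0.37 (SE 0.15) for Ppp1r1b, which encodes DARPP-32. The striatum score was -0.26 ± 0.39 (SD, n = 9) in KO and 0.23 ± 0.32 (SD, n = 9) in WT, a difference of -0.49 (SE 0.17, exact permutation p = 0.0126). It was -0.55 within array set 1 (exact permutation p = 0.0317) and -0.48 within array set 2 (exact permutation p = 0.143), with 4 or 5 arrays a group, and -0.51 pooled over the sets (permutation within sets, p = 0.0087).

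**Figure D3:**
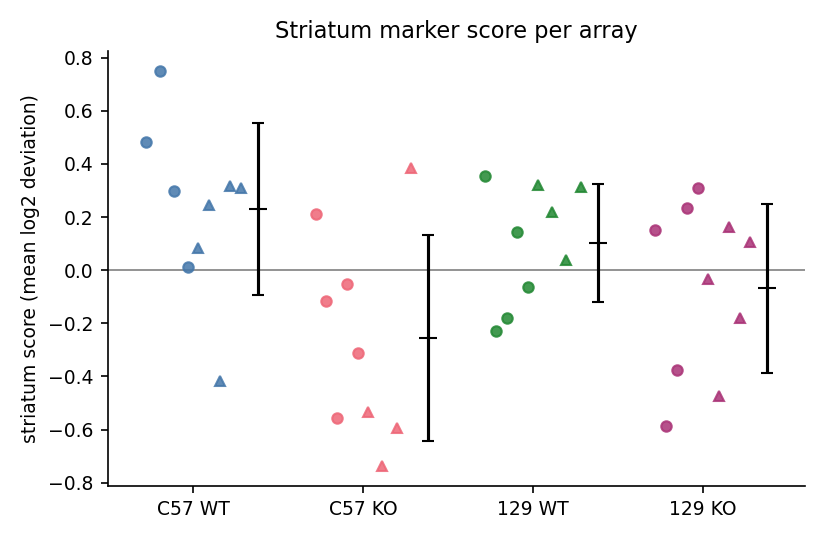
Striatum marker score (mean log2 deviation of 14 genes from their own means, vertical axis) per array in the 4 groups, with circles for array set 1, triangles for array set 2 and bars for mean ± SD. Group means were 0.23 in C57 WT, -0.26 in C57 KO, 0.10 in 129 WT and -0.07 in 129 KO, and the ranges of KO and WT arrays overlapped in both strains.

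Among the other lists in C57, the 15 myelin markers had a mean of -0.12 (camera adjusted p = 1.15e-05, but adjusted p = 0.458 with an estimated correlation). The 28 genes of the mitochondrial respiratory chain had a mean of -0.03 (camera adjusted p = 0.00413, and adjusted p = 0.573 with an estimated correlation). In both lists 0 members passed adjusted over the list alone. The ER stress list had a mean of 0.00 over 31 genes (adjusted p = 0.348), and calcium stores and buffers -0.02 over 20 (adjusted p = 0.110). Growth hormone and IGF genes had a mean of 0.02 (adjusted p = 0.676), GABA genes 0.03 (adjusted p = 0.582), glutamate genes 0.04 (adjusted p = 0.543) and monoamine genes -0.07 (adjusted p = 0.0743). Neuropeptides were at 0.01 (adjusted p = 0.348), early genes at -0.05 (adjusted p = 0.0743), and the neighbours of Wfs1 at 0.00 (adjusted p = 0.385). Markers of astrocytes (0.04, adjusted p = 0.348), microglia (0.01, adjusted p = 0.676), vessels (-0.07, adjusted p = 0.0631), choroid plexus (-0.08, adjusted p = 0.0970), hippocampus (0.09, adjusted p = 0.0970 and 0.369 with an estimated correlation), thalamus and hypothalamus (-0.03, adjusted p = 0.582) and cortical layers (-0.02, adjusted p = 0.348) did not pass with camera. Fry, which asks whether a list moves one way without comparing it with other genes, called 2 lists in C57, striatum markers lower (adjusted p = 0.0218) and hippocampus markers higher (adjusted p = 0.0218).

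The genes named beforehand did not pass in C57. Hspa5, the ER chaperone BiP, differed by 0.06 (SE 0.09), Ddit3, the stress factor CHOP, by -0.04 (SE 0.06) and Gabra2, a GABA-A receptor subunit, by -0.01 (SE 0.08). Prl (-0.10, SE 0.09) and Trpm8 (0.04, SE 0.06), a cold-sensing channel, lay below the filter. Gh, which encodes growth hormone, differed by 0.00 (SE 0.15) on its brightest probe set. The count of 14 depended on single arrays. It was 9 without KO array 3, 7 without KO array 7, 9 without WT array 25, 9 without WT array 26, 6 without WT array 33 and 7 without WT array 42. With array set as a block 15 genes passed, and 4 and 5 passed within sets 1 and 2.

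The comparison of KO with WT in 129 asked the same question on the background that the series names as 129S6. Only Wfs1 passed in limma (0 higher, 1 lower), and 279 genes had an unadjusted p under 0.05. For 98.8% of the genes the 95% confidence interval lay within 0.50 of 0. Abhd1 differed by 0.01 (SE 0.11), Drc1 by 0.05 (SE 0.07), Lgi2 by -0.07 (SE 0.10) and Ccr6 by 0.21 (SE 0.14). Hspa5 (-0.08, SE 0.09), Ddit3 (-0.03, SE 0.06), Gabra2 (-0.08, SE 0.08), Prl (0.07, SE 0.08) and Trpm8 (-0.04, SE 0.06) did not pass. With array set as a block, within set 1 and within set 2, 1 gene passed.

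Early genes induced by activity, such as Fos and Egr1, had a mean of -0.14 over 24 genes in 129 (camera adjusted p = 8.63e-06, but adjusted p = 0.908 with an estimated correlation). The 14 striatum markers had a mean of -0.17 (camera adjusted p = 0.000333, and adjusted p = 0.908 with an estimated correlation). In both lists 0 members passed adjusted over the list alone. The striatum score differed by -0.17 (SE 0.13, permutation p = 0.196), with -0.06 in array set 1 (exact permutation p = 0.794) and -0.31 in array set 2 (exact permutation p = 0.0635). The other lists did not pass, the nearest being myelin markers with a mean of -0.07 (adjusted p = 0.0507).

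Gh was also read on each of its 4 probe sets, a step chosen after the values had been seen. On the dimmest of them, KO exceeded WT by 0.28 in C57 (exact permutation p = 0.00165, adjusted p = 0.00660 over 8 tests) and by 0.63 in 129 (permutation p = 0.000801, adjusted p = 0.00641). Array 56 of 129 KO was the highest of all arrays on every Gh probe set and also on that of Prl, another pituitary hormone gene (3.28, with the next array at 2.99). Without it the 129 difference was 0.39 (exact permutation p = 0.00152). The group means on that probe set lay between 2.31 and 3.07, below the filter at 3.6. On the other 3 probe sets the differences ranged from 0.00 to 0.42, with adjusted p from 0.175 to 0.968. Without array 56 the 129 differences on these went from 0.39 to 0.15, from 0.42 to 0.17 and from 0.08 to -0.07.

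Over both strains together, 3 genes passed, 2 higher and 1 lower, with 647 at an unadjusted p under 0.05. The Wfs1 signal fell by 6.25 (SE 0.07, limma adjusted p = 2.55e-42), again to a KO signal below the filter. Abhd1 rose by 0.70 (SE 0.08, adjusted p = 2.14e-07) and Drc1 by 0.35 (SE 0.05, adjusted p = 6.40e-05), where the differences in 129 alone were 0.01 and 0.05. Hspa5 (-0.01, SE 0.06), Ddit3 (-0.03, SE 0.04), Gabra2 (-0.04, SE 0.06), Gh (0.04, SE 0.11), Prl (-0.02, SE 0.06) and Trpm8 (0.00, SE 0.04) did not pass. Striatum markers fell by a mean of 0.33 (camera adjusted p = 6.43e-24, and adjusted p = 0.0303 with an estimated correlation). Adjusted over the list alone 13 of the 14 were lower. Myelin markers had a mean of -0.10 (camera adjusted p = 1.96e-06, and adjusted p = 0.362 with an estimated correlation). Early genes had a mean of -0.09 (camera adjusted p = 1.61e-05, and adjusted p = 0.362 with an estimated correlation) and respiratory chain genes -0.02 (camera adjusted p = 0.00804, and adjusted p = 0.529 with an estimated correlation). Hippocampus markers had a mean of 0.06 (camera adjusted p = 0.0465, and adjusted p = 0.127 with an estimated correlation), and fry called them higher (adjusted p = 0.0217) and striatum markers lower (adjusted p = 0.0302). Counts adjusted over the list alone were 0 for myelin, early and hippocampus genes and 1 for the respiratory chain. With array set as a block 4 genes passed, with 2 in set 1 and 1 in set 2. The count was 5 without C57 KO array 1 and 5 without C57 WT array 40.

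The difference between the KO effects asked whether the strains respond differently. It passed in 2 genes, 2 higher and 0 lower, with 437 at an unadjusted p under 0.05. The effect on Abhd1 was larger in C57 by 1.37 (SE 0.15, limma adjusted p = 7.10e-07) and that on Drc1 by 0.59 (SE 0.10, adjusted p = 0.00256). Both genes lie on the Wfs1 chromosome, and their C57 KO signals (5.88 and 6.80) lay near those of 129 WT (5.95 and 6.69). Hspa5 (0.13, SE 0.13), Ddit3 (-0.01, SE 0.09), Gabra2 (0.07, SE 0.12), Gh (-0.08, SE 0.21), Prl (-0.17, SE 0.12) and Trpm8 (0.08, SE 0.09) did not pass. For the striatum markers the difference averaged -0.32 (camera adjusted p = 4.09e-09, but adjusted p = 0.746 with an estimated correlation), and 0 of 14 passed adjusted over the list alone. Permuting the labels within strains gave p = 0.193 for their score. Across genes other than Wfs1, the KO effects in C57 and in 129 had a Pearson correlation of 0.0667 and a Spearman correlation of 0.0441, against a range of -0.295 to 0.4 for the former in 99 shuffles (permutation p = 0.670). Genes are not independent replicates. None of the 30 tested neighbours of Wfs1 passed for KO in 129 or for the difference between the KO effects (Fisher's exact p = 1 for each), but with the mean of probe sets a neighbour passed for the latter (3.85%, Fisher's exact p = 0.00632). With array set as a block 2 genes passed, with 1 in set 1 and 0 in set 2. Without C57 KO array 5 the count was 4.

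The WT groups were compared to measure the strain difference itself. Here 269 genes passed, 127 higher and 142 lower in 129, with 1511 at an unadjusted p under 0.05. Of these, 86 differed at least 1.5-fold and 30 at least 2-fold, and 39 lie on the Wfs1 chromosome. Higher in 129 were Xaf1, an inhibitor of the apoptosis blocker XIAP, by 2.25 (SE 0.43, limma adjusted p = 0.00196), Gdpd3, a lysophospholipase, by 1.64 (SE 0.41, adjusted p = 0.0225) and Abhd1 by 1.45 (SE 0.11, adjusted p = 6.96e-12). Stbd1, which binds glycogen, was higher by 1.3 (SE 0.15) than a C57 WT signal of 2.95, below the filter, Cuedc1 by 1.19 (SE 0.26), Rab39b, a small GTPase of vesicle traffic, by 1.15 (SE 0.32), Lsm11, a part of the U7 particle that trims histone transcripts, by 1.14 (SE 0.17) and Adat2, a tRNA deaminase, by 1.01 (SE 0.28).

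Lower in 129 were the probe set named Mir1931, at -3.31 (SE 0.37), and Rpgrip1, a photoreceptor cilium protein, at -3.18 (SE 0.43). Galc, the lysosomal galactosylceramidase that breaks down myelin lipids, was at -2.86 (SE 0.40) and Ang, which encodes angiogenin, at -1.84 (SE 0.36). Rmst, a long noncoding RNA, was at -1.61 (SE 0.23), Mboat2, a lysophospholipid acyltransferase, at -1.52 (SE 0.19), Nmnat1, a nuclear enzyme of NAD synthesis, at -1.47 (SE 0.38) and Krt12 at -1.44 (SE 0.21). The calls of Rab39b (adjusted p up to 0.100), Adat2 (up to 0.106) and Nmnat1 (up to 0.0811) were lost under some alternatives, single arrays left out among them, and that of Gdpd3 (up to 0.0546) with 1 array left out. Fitted on the WT arrays alone, 16 of 19 named genes kept their calls, and Adat2 (limma adjusted p = 0.0659), Nmnat1 (0.0951) and Slc4a4 (0.0749) lost them. In 129 WT the signals of Mir1931 (2.34), Galc (2.95), Ang (2.72) and Rmst (3.44) lay below the filter at 3.6. For these and for Stbd1 the differences are therefore in signal, and their order of size is not secure. They would be lower limits for transcript only where the probes read both strains alike, which was not tested. Several of these genes varied far more in C57 than in 129. Galc had an SD of 1.25 in C57 WT, where array 28 alone was low (2.86), and 0.15 in 129 WT. Xaf1 had SDs of 1.23 and 0.22.

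**Figure D4:**
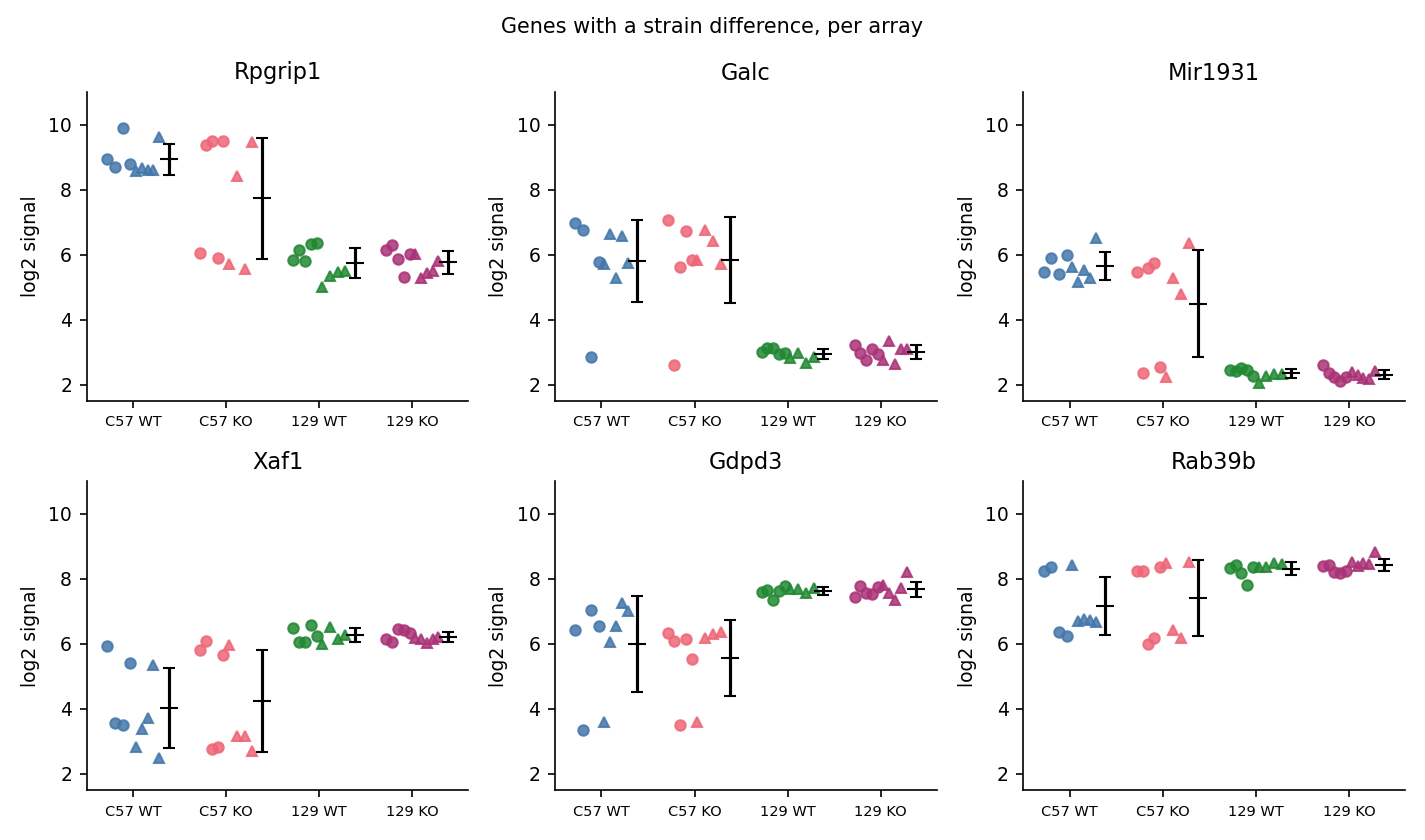
Signals (log2, vertical axes) of 6 genes with a strain difference in each array of the 4 groups, with circles for array set 1, triangles for array set 2 and bars for mean ± SD. C57 arrays lay at separate levels, for Rpgrip1 and Mir1931 only among the KO arrays, while 129 arrays lay closer together. Galc had an SD of 1.25 in C57 WT, where only array 28 was at the lower level, and 0.15 in 129 WT. For Rpgrip1 the SD was 0.49 in C57 WT and 0.47 in 129 WT.

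Between the strains 5 lists were called with the preset correlation, 0 with an estimated correlation and 0 with fry. The 15 myelin markers had a mean of -0.19 (camera adjusted p = 1.65e-06, but adjusted p = 0.430 with an estimated correlation), and 0 of 15 passed adjusted over the list alone. The 14 microglia markers had a mean of -0.12 (camera adjusted p = 0.000216, and adjusted p = 0.322 with an estimated correlation). Adjusted over the list alone, 5 of these were lower, the complement genes C1qa (-0.25), C1qb (-0.31) and C1qc (-0.23), the protease Ctss (-0.26) and the adaptor Tyrobp (-0.24). Astrocyte markers had a mean of -0.08 (camera adjusted p = 0.00707, and adjusted p = 0.322 with an estimated correlation). Their member Slc4a4, a bicarbonate transporter, passed over all genes at -0.26 (SE 0.07) and was the only 1 of 14 to pass adjusted over the list alone. Vascular markers had a mean of -0.09 (camera adjusted p = 0.0339, and adjusted p = 0.527 with an estimated correlation), with 0 of 15 adjusted over the list alone. Striatum markers had a mean of -0.13 (camera adjusted p = 0.0339, and adjusted p = 0.702 with an estimated correlation), and 1 member passed adjusted over the list alone.

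Outside the called lists, Htr1d, a serotonin receptor, was at -0.22 (SE 0.06, limma adjusted p = 0.0452), and Jakmip1, near Wfs1, at -0.29 (SE 0.07, adjusted p = 0.0207). The Htr1d call was lost with no filter (adjusted p = 0.0588), median centring (0.0515), the mean of probe sets (0.237), eBayes with trend and robust (0.0656) and single arrays left out (up to 0.107). The calls of Jakmip1 (adjusted p up to 0.051) and Slc4a4 (up to 0.0605) were lost with single arrays left out. With array set as a block 283 genes passed, and 59 and 117 passed within sets 1 and 2. Without the 3 arrays least like their group (129 WT 73, 129 KO 59 and C57 KO 10) 326 passed, and the KO comparisons gave 14 in C57, 1 in 129, 3 over both and 2 for the difference.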

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

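Chosen only after their results were seen were the slope on the Wfs1 chromosome, the 129 change of the genes called in C57, the check of other probe sets, the striatum score in 129, between strains and within array sets, all tests of separate levels, the neighbour count without 3 arrays and both kinds of splits.

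In the C57 KO arrays 12 of the 14 called genes lay on the chromosome of Wfs1, as did 17 of 29 calls with every probe set and 18 of 40 with 3 residual components. The larger counts thus held 12 and 22 calls elsewhere or without a known place. With every probe set the calls are of probe sets, including those with several gene symbols or none, which were not placed on a chromosome. A change from loss of Wfs1 alike in both strains is argued against by the 13 called genes other than Wfs1. Their median signed change was 0.488 in C57 and 0.012 in 129 (95% bootstrap interval over genes, -0.083 to 0.05). Genes are not independent replicates, so this interval does not measure the spread between samples. The genes were chosen by passing in C57, which raises their C57 value. Over all genes, the difference between the strains passed in limma for Abhd1 and Drc1 only. A candidate explanation of the calls on the Wfs1 chromosome is 129 DNA carried along with the targeted allele. To test it, the C57 WT arrays were divided so that no array served both sides. The slope of the KO change on the difference of 129 from C57 WT arrays was 0.484 on that chromosome (39 genes). Elsewhere it was 0.0276 (270 genes). With the parts exchanged, the slope was 0.737 (18 genes) against 0.00534 (165 genes). Genes were chosen anew for each division. These 39 therefore need not be the 39 genes of that chromosome called between the WT groups. Whether the arrays read different transcript levels or a probe sequence that differs between strains cannot be told apart. Of the 13 called genes, Ccr6 and Ypel1 elsewhere included, 10 had 1 probe set past the filter. Of 6 other probe sets of the rest 1 moved alike, and it belongs to Ypel1. Those of Ppp1cb and Lgi2, which lie on the chromosome, did not move alike. In C57 KO they differed by 0.745, -0.062 and 0.004 for Ppp1cb and by 0.18 for Lgi2. Between strains the first was 0.818 higher in 129 WT. How far such a segment would reach was not tested: of the 30 nearest tested neighbours 0 were called in C57 KO, but only 1 differed between the strains and so could show 129 DNA, namely Jakmip1, at -0.31 in C57 KO (adjusted p = 0.0769) and -0.29 between strains, and a neighbour was called with the mean of probe sets (3.85%, Fisher's exact p = 0.0188), with the first residual component (3.33%, p = 0.0405) and without 3 arrays (3.33%, p = 0.0294).

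The striatum markers were lower in C57 KO. An array set effect is argued against, since the score differed by -0.55 within set 1 and by -0.477 within set 2, and by -0.51 pooled over both (permutation within sets, p = 0.0087), although set 2 alone did not pass (exact permutation p = 0.143). Less striatal tissue in the dissected samples may account for the lower markers. In the other 28 arrays 18 genes outside the lists followed the score, and all were lower in C57 KO. Their median ratio of observed to predicted change was 0.864 (95% bootstrap interval over genes, 0.733 to 0.957). This interval too does not measure the spread between samples. A loss or a lower activity of striatal-type cells would give the same ratio and stays open. Whether loss of Wfs1 acts alike in both strains cannot be told apart, because the score differed by -0.17 in 129 (permutation p = 0.196) and the difference between the strains was -0.32 (permutation p = 0.193).

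Some genes lay at separate levels among the C57 arrays. Gaps were sought after the fitted difference between the array sets had been removed from each gene. With a gap of at least 1 on the log2 scale, 20 genes other than Wfs1 did so among the 18 C57 arrays and 0 among the 19 129 arrays. This gap was settled after counts at 0.75 (34 and 1) and 0.5 (63 and 13) had also been seen. The counts leave out levels that follow the array sets, as for Gprin3, with a mean of 2.78 in set 1 and 5.51 in set 2. Whole arrays of 129 animals among the C57 arrays are argued against, since the C57 array nearest to 129 was on the 129 side at 77.8% of 18 genes. Array sets divided 0 of these genes. Removing the set difference beforehand works against finding such genes, so this count cannot argue against array sets. A mix of C57 and 129 DNA among the C57 animals may account for the separate levels. At a gap of 0.75, genes within 500 annotated genes of each other (11 pairs) shared their sides with a mean correlation of 0.698. On different chromosomes it was 0.0587 (permutation p = 0.0001, the smallest these permutations can give). At a gap of 0.5 the permutation p was again 0.0001 with 21 pairs, but at a gap of 1 there was a single pair with a correlation of 0.282 (permutation p = 0.142), so that gap decides nothing.

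The interaction test singled out Abhd1, with a KO effect larger in C57 by 1.37, and Drc1, by 0.59. Both lie on the Wfs1 chromosome. Abhd1 was at 4.50 in C57 WT, 5.88 in C57 KO and 5.95 in 129 WT, and Drc1 at 6.16, 6.80 and 6.69. In C57 KO both thus lay near the 129 level. A response that differs by strain and 129 DNA carried with the targeted allele cannot be told apart here. The striatum list differed between the strains by -0.32, a call lost with an estimated correlation (adjusted p = 0.746).

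Single arrays stood apart from their group in 21 of 140 group and gene combinations (35 genes). Chance gives about 1 in 20 where a group lies at a single level, which does not hold for C57 genes at separate levels. In 129 KO array 59, high values were 6.49 for Abhd1, 6.03 for Ccr6, 8.21 for Gdpd3, 8.83 for Rab39b and 7.47 for Adat2. In 129 WT array 73, the array with the highest actin 3' to 5' difference, Cfap69 was low at 3.78, Rab39b low at 7.81 and Jakmip1 high at 9.78. Gh was high at 5.42 in 129 KO array 56, and Rmst at 3.7 in 129 KO array 52. Trpm8 was low at 1.72 in 129 WT array 76 and Gdpd3 at 7.36 in 129 WT array 72. Among C57 WT arrays, Abhd1 was high at 5.37 in array 34 and Wfs1 at 9.73 in array 42, while Galc was low at 2.86 in array 28 and Krt12 at 5.55 in array 37. Among C57 KO arrays, Galc was low at 2.6 and Nmnat1 at 3.65 in array 2, Adat2 at 4.36 and Mboat2 at 6.28 in array 17, and Krt12 at 5.61 in array 8. The C57 values of Galc, Nmnat1 and Adat2 given here are those on the smaller side, within their group, of the separate levels described above.

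The arrays were split anew for each comparison, and splits calling as many genes as the real one were counted, the real one included. In C57 these were 2 of 100 (real count 14, highest other 744), in 129 4 of 100 (1 and 39), over both strains 2 of 100 (3 and 272), for the difference 4 of 100 (2 and 310) and between strains 1 of 100 (269 and 3). These splits ignored the array sets. Splits drawn within the sets, added later, gave a count as large in 1 of 100 in C57 (highest other 6), 2 of 100 in 129 (highest other 1), 1 of 100 over both strains (highest other 2), 2 of 100 for the difference (highest other 12) and 1 of 100 between strains (highest other 15). At the usual bound of 5 in 100, counts as large were rare in C57, over both strains and between strains, and for the difference, with 4 of 100 in the first kind of split, only narrowly. The counts in C57 and over both strains include Wfs1, which defines the groups. Without it 13 remain in C57, above the highest other split within the sets. Over both strains 2 remain, no more than the highest other split within the sets, so this count does not exceed all of them. There 3 other splits called 1 or more genes. In 129 the real count is Wfs1 itself, so its splits say nothing about other genes. Single splits with far more calls than the real one may reflect a structure of the samples that the groups do not give, and what sets those splits apart was not tested.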

How the results depend on the processing

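Array set as a block or alone, the first 3 residual principal components, the actin covariate, the whole chromosome, leaving out 3 arrays and, for named genes, only the groups compared were chosen after the data were seen; the other settings were planned. A pseudocount was not varied, since the values were already log2. Wfs1 kept its direction and call in all 106 values, from -6.36 to -6.23 in C57 and from -6.31 to -6.13 in 129. Of 533 values for 49 results of named genes, 486 kept direction and call, 46 lost the call and 1 changed sign: the C57 change of Ppp1cb was 0.068 with the mean of its probe sets, which did not move alike. These settings did not include a fit on only the groups compared, where 5 of 11 named genes in C57 and 3 of 19 between strains lost the call. Counts with every probe set are of probe sets, not genes. In the C57 comparison, 29 passed with every probe set, 7 with only the groups compared, 4 and 5 in array sets 1 and 2, and 40 with 3 components. Over both strains 5 passed after quantile normalization, 9 with every probe set, 10 with array weights, 1 in set 2 and 8 with 3 components. For the difference, 9 passed with every probe set, 1 in set 1, 0 in set 2 (limma) and 6 with 3 components. Between strains, 697 passed with every probe set, 678 with array weights, 59 in set 1, 117 in set 2 and 714 with 3 components. Settings with fewer arrays or more probe sets differ by construction, and otherwise the cause was not tested. The share of changed genes near Wfs1 was 3.85% in C57 and 3.85% for the difference with mean probe sets, 3.33% in C57 with 1 component, 3.33% without 3 arrays, and over the whole chromosome 1.34% in C57 and 0.244% for the difference. Lists called in C57 numbered 1 with an estimated correlation, 2 with fry, 5 with the 60th percentile filter and 5 after median centring. In 129 they numbered 0 with an estimated correlation, 0 with fry and 5 without 3 arrays. Over both strains these were 1, 2 and 8. For the difference and between strains they were 0 with an estimated correlation and 0 with fry. Leaving out 1 array gave 6 to 17 genes in C57 (9 without KO 3, 7 without KO 7, 9 without WT 25, 9 without WT 26, 6 without WT 33, 7 without WT 42). It gave 1 to 1 in 129, 3 to 5 over both (5 without C57 KO 1 or C57 WT 40), 2 to 4 for the difference (4 without C57 KO 5) and 187 to 342 between strains. Wfs1 moved from -6.36 to -6.23 in C57 and from -6.28 to -6.17 in 129. Low signal limits the reading of transcripts below the filter, such as Prl and Trpm8.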

Other observations

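The comparison of marker scores between single arrays was chosen after the values had been seen. Choroid plexus markers, Ttr and Kl among them, stood highest in C57 WT array 34, with a score of 1.451, and in 129 WT array 72, at 1.15, followed by C57 WT array 33 at 0.456, while the list did not pass in any comparison. No explanation of these scores was tested.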
